A study of Brassica napus with 110 samples.

How the data were processed

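RNA libraries of 3 materials at 7 times of salt treatment, 63 in all, were analysed through a table of gene counts, one for all of them. The series lists 110 samples, of which 42 ATAC-seq samples and 5 samples of whole-genome or bisulfite sequencing were not analysed here. The values are raw counts of reads per gene as deposited, with whole numbers in every column and totals that differ between libraries. Per the submitters' processing notes, HISAT2, Bowtie2, BWA and featureCounts were used in the study, and their versions and roles are not given in the sources used here. The deposited table has the layout of featureCounts output. The genome build and annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Coordinates are those of the deposited table, in its own assembly, with each gene's whole span as its length for all 100919 genes. Reads of near-identical gene copies, including homoeologous copies on the A and C chromosomes, may have been counted at one copy or left out, so single genes of such pairs are uncertain. The same holds for overlapping and antisense genes.

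Groups and replicate numbers were taken from the sample labels. That HZ62 is the hybrid of 2063A and B409 is general knowledge of the cultivar together with the series title and is in no label. All columns of the table were matched to a sample by name. Libraries of a group were compared pair by pair for repeated deposits: over genes with a summed count of at least 20, the mean chi-square per gene ran from 1.37 to 10.9 over 63 pairs, and 0 pairs were identical. Each library was kept as its own replicate.

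Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and the alternative test used DESeq2 1.42.0. Input was read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9. Genes were filtered with filterByExpr, which kept 58909 genes, scaled by trimmed mean of M-values and fitted with robust quasi-likelihood in 1 model with a mean for each of the 21 groups. Within this model each later time was compared with 0 h in each material (18 contrasts), B409 with 2063A at each time (7 contrasts), and HZ62 with each parent. Interaction contrasts compared the log2 response of B409 with that of 2063A, and of HZ62 with the mean of both parents. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 per contrast and a log2 fold change of at least 1 in size. For the comparison with the mid-parent, the counts of 2063A and B409 libraries of the same number were scaled to a common effective size, averaged and rounded, and HZ62 was tested against these libraries at a fold of at least 1.5. Averaging lowers the counting noise of these libraries. A gene counted as beyond both parents when both contrasts passed the adjusted p in the same direction, with no fold minimum. Both contrasts use the same HZ62 libraries, so their chance deviations are shared.

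Overlaps between materials were tested with Fisher's exact test for each pair. The share of counts on A chromosomes was compared by permutation within times with 100000 draws, and between times by the exact permutation test of 3 against 3 libraries, both two-sided. The shares of B409-type transcripts were compared between 0, 1, 3 and 24 h by an exact permutation test over all partitions of the 12 libraries, by the sum of squares between times. Genes of a single parent had at least 1 CPM (counts scaled to the effective library size) in all 21 libraries of one parent and a mean under 0.05 in the other. Blocks were found after the data were seen, on 48414 genes with a mean of at least 1 CPM in a parent at 6, 12 and 48 h. A block expressed mainly in one parent needed windows of 20 genes with a share of at least 0.6 over 8-fold apart. A block with a smaller shift needed a running median over 41 genes beyond 0.45 on the log2 scale. Blocks held at least 30 genes, and ratios used a pseudocount of 0.1 CPM. B409-type genes were those with at most 2% of the B409 level in 2063A at 6, 12 and 48 h and at least 2 CPM in HZ62.

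The rule for named genes was set before the data were examined. For the salt response at 1, 24 and 48 h it took genes past the thresholds in the same direction in all 3 materials. They had a mean of at least 1 CPM and were ranked by mean log2 fold change. The rule also covered the parental difference, genes beyond both parents and the response differences. Because the IDs are not paired with names, at most 2 IDs that rose and 2 that fell were to be printed. Using only those of the 24 h salt comparison was a further choice that the rule did not make. The gene lists fixed beforehand (such as abscisic acid, proline, photosynthesis and ion transport genes) could not be matched to IDs, so no list was tested. The comparisons, their designs and most alternatives were also fixed before the data were examined. The alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, the replicate number as a block, each replicate number left out, each single library left out, a fit of each material alone, the log2-scale mid-parent and a fold minimum beyond both parents.

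The limit that depth sets on the calls was not measured by level of expression. The steps were tested on simulated counts, of which 56900 genes passed the filter, with 200 genes changed in HZ62 at 24 h. The counts were drawn with the real library totals and the trend of the dispersion. Each parent had a single mean per gene for all times, and HZ62 had the mean of its parents. Spread of single genes or libraries beyond the trend was not simulated, so the rates below hold for simpler data than the real ones. The salt comparison of HZ62 at 24 h called 0% of the genes changed 1.5-fold, 46.3% of those changed 2-fold and 100% of those changed 4-fold, as its threshold lies at 2-fold. The mid-parent comparison at 24 h called 46.3%, 95.5% and 100%, with 6 unchanged genes called, and the hybrid interaction at 24 h called 2.99%, 43.3% and 98.5%, with 5 unchanged genes called. In the simulated B409 comparison at 24 h, where nothing was changed, edgeR called 0 genes, with 5% of genes at an unadjusted p under 0.05.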

Results

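The series followed 3 materials of oilseed rape (Brassica napus, an allotetraploid with an A and a C subgenome), named 2063A, B409 and HZ62, through a salt treatment. Plants in Hoagland nutrient solution were sampled before (0 h) and after 1, 3, 6, 12, 24 and 48 h of treatment with NaCl, given as 220 mM in the labels and as 1.25% in the series text, and polyadenylated RNA was sequenced. The labels give the tissue as young leaf in one field and as cotyledon in another. This gave 63 RNA libraries in 21 groups of 3 libraries. The total count per library ran from 12937413 to 33495798, with a median of 20817408. Of 100919 genes in the table, 58909 had enough counts to be tested and 14876 had no count in any library. The common biological coefficient of variation between libraries of a group was 6.1%. Nothing in the labels says whether the 3 libraries of a group came from separate plants, so each p-value measures the spread between these libraries only, which may be technical. The title of the series names heterosis for salt tolerance, and 2063A and B409 were treated as the parents of HZ62. The gene IDs were not paired with gene names, and none of the 100919 matched in a table of 123214 named genes of the species, so genes are described by chromosome region.

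The first question was how the transcriptome changed with time in salt within each material. In 2063A and HZ62 the number of changed genes was lowest at 1 h, highest at 3 h and lower again at 24 h. In 2063A, 4981 genes rose and 2089 fell at 1 h, 10709 rose and 10109 fell at 3 h, and 4861 rose and 3671 fell at 48 h. In HZ62, the corresponding numbers were 3133 and 2010 at 1 h, 8128 and 9298 at 3 h, and 4630 and 3160 at 48 h. In B409, 7688 genes rose and 8746 fell at 3 h and 6608 rose and 4542 fell at 24 h, but at 48 h 8971 rose and 7352 fell, close to the 16434 genes of 3 h, which were 15359 without the libraries of replicate 1. The total of 16323 genes in B409 at 48 h compared with 8532 in 2063A and 7790 in HZ62. An exchange of the 24 h and 48 h labels in B409 stays open, as described below. A change was called at an adjusted p under 0.05 in the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment, together with a log2 fold change of at least 1 in size. No library without salt was taken after 0 h, so changes with salt, age and hour of day were measured together.

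**Figure D1:**
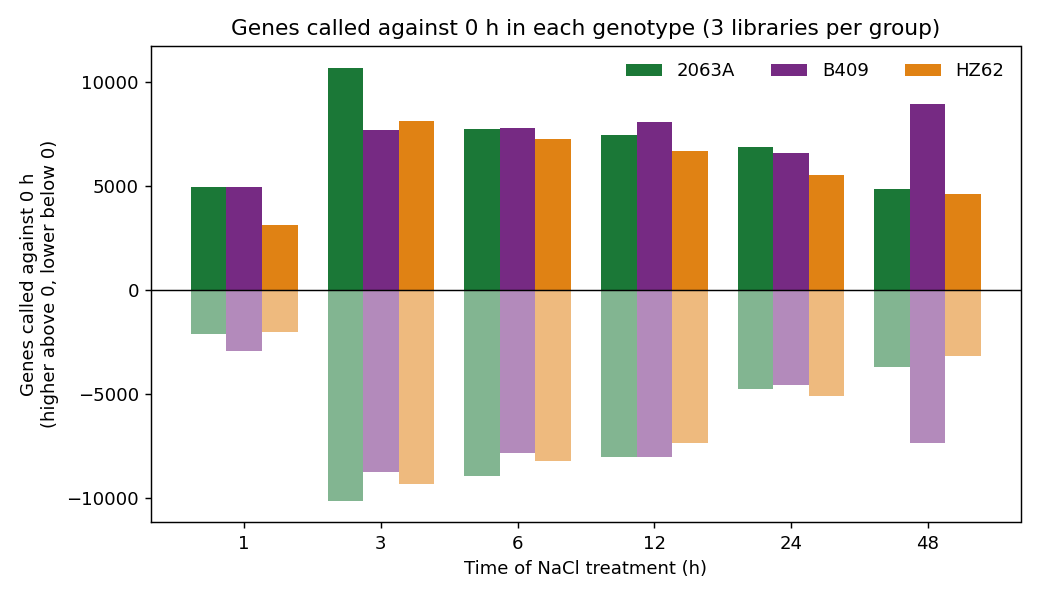
Number of genes called against 0 h (vertical axis, genes that rose above 0 and genes that fell below 0) at each time of NaCl treatment in hours (horizontal axis), with 1 bar per material fitted on 3 libraries per group. The B409 bars at 48 h reach 8971 genes up and 7352 down, against 4861 and 3671 in 2063A and 4630 and 3160 in HZ62.

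At 6 h, 7737 genes rose and 8909 fell in 2063A, 7823 rose and 7832 fell in B409, and 7278 rose and 8185 fell in HZ62. At 12 h, the totals were 15464 genes in 2063A, 16106 in B409 and 14064 in HZ62. Among the genes called at 1 h, 70.5% rose in 2063A, 63% in B409 and 60.9% in HZ62. The median size of the log2 change over all tested genes in HZ62 went from 0.289 at 1 h to 0.624 at 3 h and back to 0.347 at 48 h, while in B409 it was 0.448 at 24 h and 0.582 at 48 h. Changes are relative to the normalization factors of edgeR, which at 12 h moved the median gene by 0.414 in 2063A, 0.41 in B409 and 0.301 in HZ62 on the log2 scale against plain scaling by the library total. Of the genes that rose in 2063A, 845 of 4981 at 1 h, 884 of 10709 at 3 h and 683 of 6914 at 24 h lay in 4 chromosome blocks where 56.3% to 96.4% of the expressed genes were over 8-fold higher in B409 than in 2063A at 6, 12 and 48 h. In the 2063A libraries of 1, 3 and 24 h, B409-type transcripts stood at 12.8%, 20% and 16.5% of their HZ62 level.

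At 24 h the strongest rises shared by the 3 materials included a C04 gene and an A02 gene. BnaC04G0476800ZS (chromosome C04, 60424859 to 60426749) went from 0.213 ± 0.0729 to 155 ± 4.07 CPM (counts scaled to the effective library size) in HZ62 (mean ± SD, n = 3), a log2 change of 9.54 with an adjusted p of 6.3e-81 in the edgeR quasi-likelihood test. The 0 h mean in HZ62 rests on 14 counts, so the size of this change is uncertain. In 2063A it went from 0.0509 ± 0.0448 to 153 ± 0.432 and in B409 from 0.0836 ± 0.0757 to 75.8 ± 5.12 CPM (n = 3 each), with 2 and 4 counts behind the 0 h means. BnaA02G0046800ZS (A02, 2615915 to 2617686) rose by 10.82 in HZ62, 10.53 in 2063A and 8.25 in B409 on the log2 scale, from 0 h means resting on 21, 12 and 30 counts. Its level at 24 h was 558 ± 12.8 CPM in HZ62 and 185 ± 4.49 in B409 (SD, n = 3). The edgeR adjusted p of BnaA02G0046800ZS was 5.3e-60 in HZ62, 8.9e-57 in 2063A and 8.7e-53 in B409.

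Among the strongest falls at 24 h were 2 further genes of C04. BnaC04G0304000ZS (C04, 41254705 to 41255542) fell from 71.1 ± 1.49 to 0.088 ± 0.0395 CPM in B409 and from 28.2 ± 0.811 to 0.24 ± 0.0315 in HZ62 (SD, n = 3). Its log2 change was −9.48 in B409, −7.06 in 2063A and −6.82 in HZ62, with edgeR adjusted p values of 9.6e-68, 2.5e-57 and 3.1e-58. The 24 h means rest on 5, 13 and 16 counts in the same order. BnaC04G0580800ZS (C04, 68837712 to 68838714) fell from 13.3 ± 0.722 to 0.0844 ± 0.0585 CPM in HZ62 (SD, n = 3), with 6 counts behind the 24 h mean. This was a log2 change of −7.1 with an edgeR adjusted p of 7e-47. In 2063A it stood at 11 ± 1.03 at 0 h and at 0.0163 ± 0.0282 at 24 h, and in B409 at 24.4 ± 1.96 and 0.0207 ± 0.0358 (SD, n = 3), where the 24 h means rest on 1 count each.

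The materials shared a large part of their salt response. At 6 h, 4452 genes rose and 4853 fell in all 3 materials, where independent lists of the same lengths would share 127 and 165. At 1 h, 2083 genes rose in all 3 (22.4 for independent lists) and 530 fell (3.53). Of all genes that rose in any material, the shared fraction was largest at 6 h, with 39.4%, and lowest at 48 h, with 22.7%. Of those that fell, it was 39.6% at both 6 and 12 h and lowest at 1 h, with 10.5%. Between pairs of materials, the odds ratios of Fisher's exact test at 48 h for genes that rose were 16 for 2063A with B409, 45.9 for 2063A with HZ62 and 47.8 for B409 with HZ62. For genes that fell at 48 h they were 10.8, 35.7 and 24.3. The p-values of these tests were below the smallest number the software can hold. They treat genes, which are not independent replicates, as the units, and hold no spread between libraries. Each material had its own 0 h libraries, so the lists share no library. At 48 h, 4417 genes rose and 4504 fell past the thresholds in B409 without a call in the same direction in either of the others, a count that does not test whether the responses differed.

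The second comparison set the 2 parents against each other at each time. B409 and 2063A differed at 11215 genes before salt (n = 3 libraries each), with 49.7% of them higher in B409, and at 17336 genes at 48 h, with 54.2% higher in B409. The times between gave 11989, 14523, 12550, 13480 and 12850 genes from 1 to 24 h, by the edgeR quasi-likelihood test with the same thresholds. Many of these genes lay side by side. Blocks of neighbouring genes with a common parental difference, defined on the 6, 12 and 48 h libraries by rules set after the data were seen, held 6.83% of the tested genes but 22.8% of the differing genes at 0 h and 16% at 48 h.

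In 4 blocks most expressed genes were over 8-fold higher in B409. They covered C01 from 55744635 to 57790178, C02 from 48770 to 2311380, C02 from 54106828 to 64374965 and C09 from 63855362 to 68379807. They numbered 160 of 166 expressed genes in the C01 block, 49 of 87 at the C02 start, 361 of 394 at the C02 end and 387 of 437 at the C09 end. The median log2 ratio of B409 to 2063A was 5.65 in the C01 block (quartiles 4.41 and 6.79), 5.53 at the C02 end (4.17 and 6.74) and 5.56 at the C09 end (4.08 and 6.95). At the C02 start it was 3.77, with quartiles of 0.1 and 5.36, so part of its genes were expressed about alike in the parents. These 4 blocks held 957 of the 1915 genes that were over 8-fold higher in B409 among 48414 expressed genes. At 0 h, 1240 of the 1413 tested genes in them were called higher in B409 and 11 lower. In 4 smaller blocks most genes were over 8-fold higher in 2063A, on C02 from 64423384 to 65266832, on C03 from 1591571 to 2084664 and from 2436722 to 3087215, and on C09 from 197345 to 1279687. Their median log2 ratios of B409 to 2063A were −4.34, −4.09, −4.41 and −3.56.

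Other blocks showed a smaller shift, 12 of them higher in 2063A, with medians of −1.81 to −0.54, and 9 higher in B409, with medians of 0.49 to 1.14. The A01 end from 34686875 to 37573399, the A02 region from 29669692 to 34369001 and the A10 end from 23627509 to 26579029 were higher in 2063A. Their median log2 ratios of B409 to 2063A were −0.87 over 231 genes (quartiles −1.11 and −0.53), −1.11 over 350 genes (−1.79 and −0.71) and −1.05 over 446 genes (−1.53 and −0.68). Among those higher in B409 were A03 from 1213819 to 1624069, with a median of 0.79, A03 from 1883253 to 2555389, with 1.14, and A09 from 1311408 to 2115721, with 0.66. On A09 this block lay between 2 blocks higher in 2063A, from 477812 to 1212168, with −1.58, and from 3055516 to 3856033, with −0.61. HZ62 lay close to the mean of the parents in the larger blocks. Its median log2 ratio to that mean was −0.01 in the A01 block, −0.04 in the A02 block, −0.01 in the A10 block, −0.04 in the C01 block, −0.02 at the C02 end and −0.01 at the C09 end. A01 and C01, A02 and C02, and A03 and C03 are homoeologous pairs, and the A10 end corresponds to the C09 end.

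**Figure D2:**
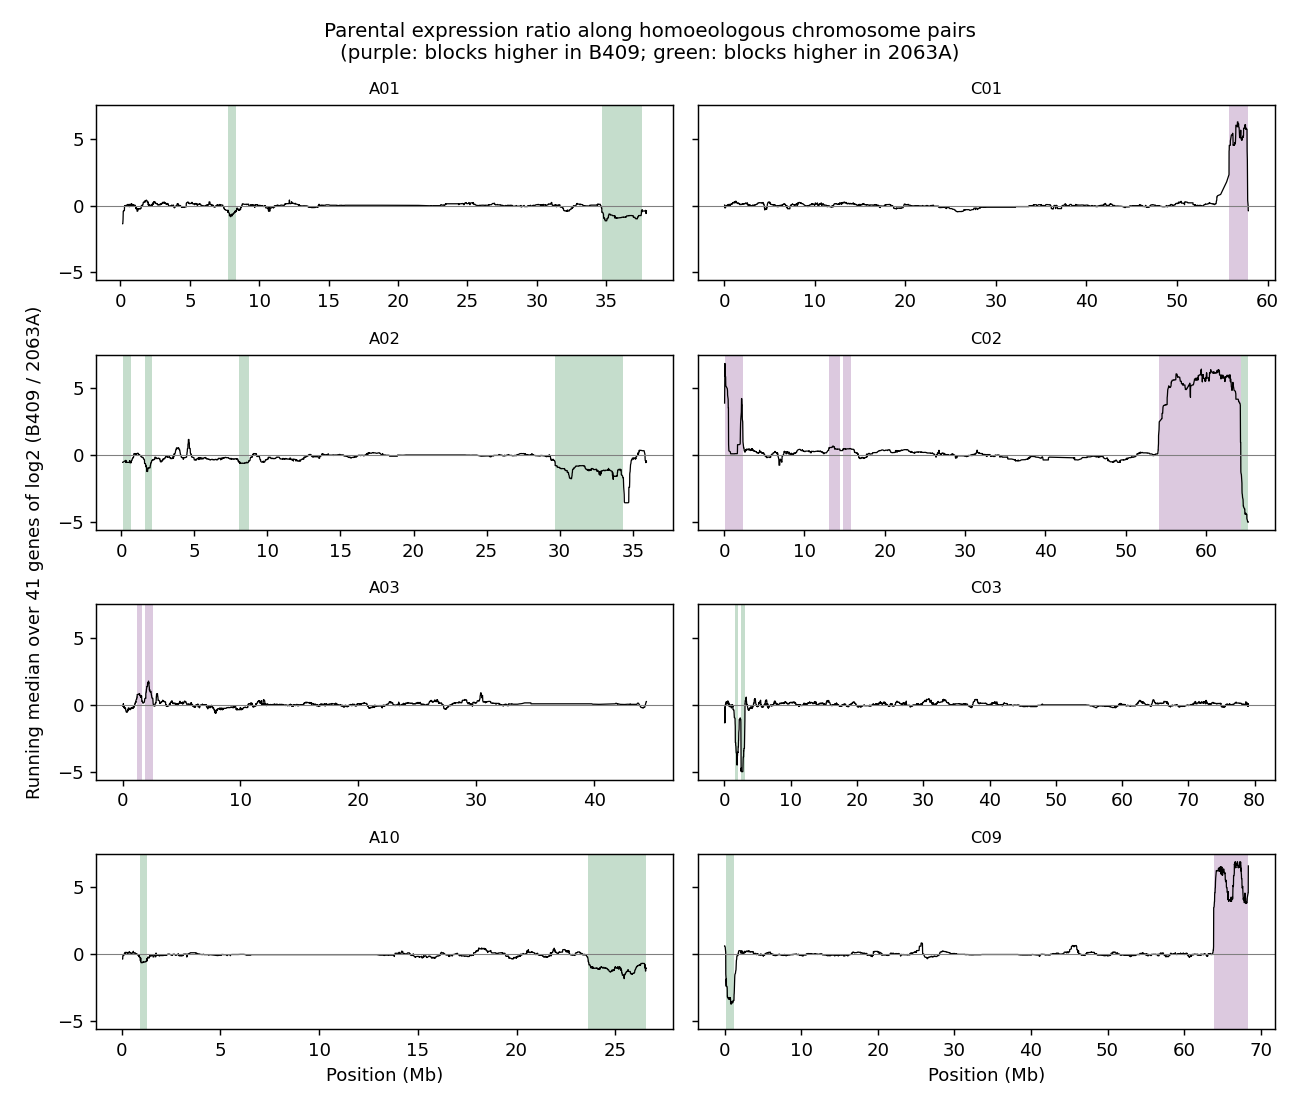
Running median over 41 expressed genes of the log2 ratio of B409 to 2063A (vertical axis) along 8 chromosomes in megabases (horizontal axis), with blocks higher in B409 shaded purple and blocks higher in 2063A shaded green. Over their genes, the C01 end block, the C02 block ending at 64374965 and the C09 end block have medians of 5.65, 5.53 and 5.56. The last block of C02, from 64423384, has a median of −4.34, and the A01, A02 and A10 blocks lie below 0.

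Transcripts of genes that only B409 and HZ62 expressed at 6, 12 and 48 h appeared in the 2063A libraries of other times. For 780 such genes, the 2063A libraries held 12.8% ± 0.128 of the HZ62 level at 1 h, 20% ± 0.138 at 3 h and 16.5% ± 0.737 at 24 h (SD, n = 3), against 2.19% ± 0.203 at 0 h. At 6, 12 and 48 h, the times used to choose the genes, the level was 0.377% to 0.609%. The blocks did not move together. At 24 h the C01 end stood at 1.78% ± 0.777 and the C09 end at 22% ± 0.813 of the HZ62 level, while at 1 h the C01 end stood at 25.6% ± 0.402 and the C09 end at 13.2% ± 0.134. The C02 start was highest at 0 h, at 11.7% ± 1.07, and stood at 0.798% ± 0.0711 at 3 h. The 210 of the 780 genes that lay outside the 4 blocks stood at 7.14% ± 0.674 at 0 h, 4.65% ± 0.386 at 1 h, 13% ± 0.444 at 3 h and 21.4% ± 0.947 at 24 h. These are shares of the summed level, carried at 0, 1 and 3 h by part of the genes. The medians over the 165 to 192 genes with at least 2 CPM in HZ62 at these times were 4.7%, 1.02%, 4.96% (quartiles 0.306% and 17.5%) and 21.3%, in the same order. At 0 h the C01, C02 and C09 ends stood at 0.631%, 0.95% and 1.03%, below the 2.19% over all genes. In the reverse direction, 391 genes that only 2063A expressed at 6 and 12 h stood in the B409 libraries at 2.63% ± 0.0262 of the 2063A level at 1 h and 1.11% ± 0.0378 at 24 h, and between 0.292% and 0.762% at the other times. These are percents of the expressing parent and not of HZ62. Against the B409 level, the 780 genes stood in 2063A at 6.67%, 11.2% and 8.79% at 1, 3 and 24 h. Between 0, 1, 3 and 24 h, times not used to choose the genes, the share over all 780 genes differed with p = 6.5e-05 in an exact permutation test of the 12 libraries, the smallest p that the 15400 partitions can give. The largest p for a single block was 0.00032, at the C01 end, which is also its Benjamini-Hochberg adjusted value over 6 tests. This test was chosen after the data were seen, takes the HZ62 level as fixed, and does not say which times differ. The labels do not say whether the 3 libraries of a time came from separate plants. Its p therefore measures the spread between libraries only and not between plants.

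Within the C02 end block, the share at 24 h stepped along the chromosome. Left of the interval from 58732859 to 58814613, 75 genes stood at 0.981% ± 0.945 of the HZ62 level, and right of it 127 genes stood at 21.5% ± 0.346 (mean and SD of the library medians, n = 3). The libraries on the left stood at 0.296%, 0.589% and 2.06%, and without replicate 3 their mean was 0.442%. At 1 h the same parts of the block stood at 13.7% ± 1.48 and 12.7% ± 0.45. At 3 h they stood at 21.8% ± 0.492 and 17.3% ± 0.396, a difference above the SD of the libraries. The place was found by a search for the largest difference of medians, so no p-value is given. The same search at 0 h and 3 h found another place, between 62995006 and 63034736, where the median over genes went from 0.431% left of it to 6.68% right of it at 0 h and from 19.9% to 10.5% at 3 h, with 18 genes on the right. At 1 h its largest step lay between 63105119 and 63107239, from 13.9% to 22.5%, with 15 genes on the right (quartiles 8.24% and 45.1%).

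**Figure D3:**
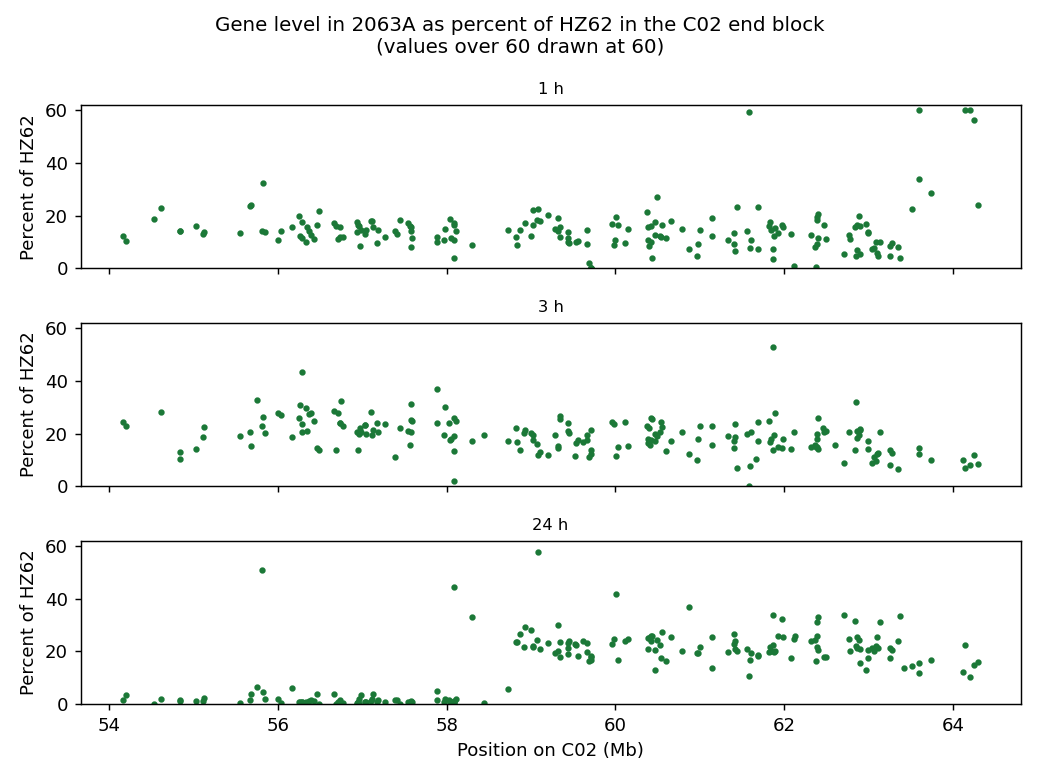
Level of each gene of the C02 end block in 2063A as percent of its HZ62 level (vertical axis, values over 60 drawn at 60) against position in megabases (horizontal axis) at 1, 3 and 24 h, with 1 point per gene from the means of 3 libraries. At 24 h the genes left of 58732859 have a library median of 0.981% and those right of 58814613 one of 21.5%.

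**Figure D4:**
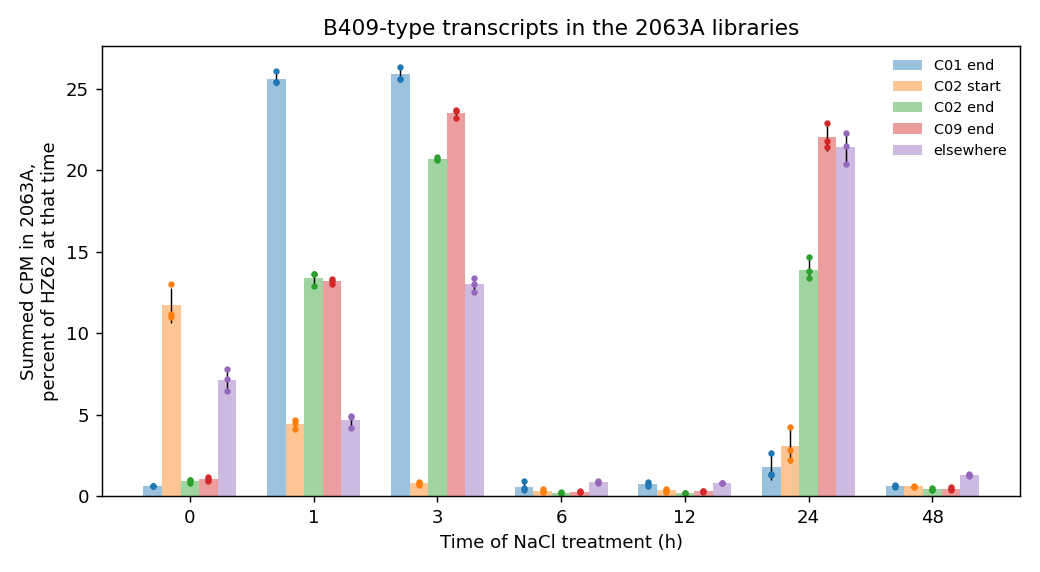
Summed CPM in the 2063A libraries as percent of HZ62 at the same time (vertical axis) against time of NaCl treatment in hours (horizontal axis), for genes nearly absent from 2063A at 6, 12 and 48 h. Bars are means of 3 libraries with SD and points are libraries; the C01 end reaches 25.6% at 1 h and 1.78% at 24 h, the C09 end 13.2% and 22%.

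The next question was whether the parents responded to salt in different ways. The largest difference between parental responses was at 48 h, when the log2 change was higher in B409 at 4827 genes and lower at 3716, by the edgeR test of the interaction between parent and time. For 78.1% of these 8543 genes the change was larger in size in B409. This comparison rests on the time labels of B409, where an exchange of 24 h and 48 h stays open. The earlier times gave 2629 genes at 1 h, 6076 at 3 h, 3230 at 6 h, 3922 at 12 h and 4951 at 24 h. At 3 h, 3964 of the 6076 genes had the lower log2 change in B409, and 25% had the larger change in B409. Of the 1556 genes with the lower change in B409 at 1 h, 724 lay in the 4 blocks with most genes over 8-fold higher in B409, as did 809 of 3964 at 3 h and 590 of 2645 at 24 h. At these times the 2063A libraries held B409-type transcripts at 12.8%, 20% and 16.5% of the HZ62 level. Without the 3099 genes that were at least 8-fold higher in B409 at 6, 12 and 48 h, an alternative chosen after the data were seen, 1597 genes differed at 1 h. Without the libraries of replicate 3, 1617 did. The 3099 genes were taken from all tested genes, without the pseudocount and the minimum of 1 CPM of the block search. They can thus include genes of low level that are not among its 1915 genes over 8-fold higher in B409.

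Where the parents differed, HZ62 mostly stood between them. Of the genes that differed between the parents, between 89.9% at 1 h and 94% at 12 h had an HZ62 mean inside the parental range. The median position of HZ62 on the scale from 2063A (0) to B409 (1) ran from 0.427 at 24 h to 0.498 at 12 h. For 323 genes expressed in every 2063A library and below 0.05 CPM on average in B409, the median ratio of HZ62 to 2063A was 0.521 (quartiles 0.484 and 0.556). For 65 genes expressed only in B409, the median ratio of HZ62 to B409 was 0.489 (quartiles 0.426 and 0.528). With the libraries of 6, 12 and 48 h alone, the lists grew to 485 and 945 genes, with median ratios of 0.488 and 0.496.

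The direction of departures from the parental mean depended on the scale of that mean. Against libraries made by averaging 2063A and B409 counts, HZ62 was higher at 1914 genes and lower at 1385 at 0 h, higher at 2025 and lower at 1546 at 6 h, and higher at 2055 and lower at 3550 at 48 h. At the other times, the higher and lower genes numbered 1839 and 2164 at 1 h, 1042 and 1586 at 3 h, 835 and 1359 at 12 h, and 1038 and 1939 at 24 h. The call needed an adjusted p under 0.05 in the edgeR quasi-likelihood test and a fold of at least 1.5. On the log2 scale of the parental mean, most of the called genes were higher in HZ62 at each time, 86.9%, 76.8%, 84%, 85.6%, 86.3%, 76.4% and 77.2% from 0 to 48 h, with 5850 higher and 885 lower at 0 h and 5849 and 1726 at 48 h, and the total exceeded the arithmetic one by over 1.5 times from 0 to 24 h. The Wald test of DESeq2 called 1459 genes at 12 h in place of 2194, and turned the majority at 1 h to higher genes, 1596 against 1508. The 2063A libraries, which enter the averages, held B409-type transcripts at 2.19% of the HZ62 level at 0 h and 20% at 3 h.

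HZ62 stood above both parents at 1845 genes and below both at 2447 before salt, with the differences from each parent past an edgeR adjusted p of 0.05. In salt, more genes stood above than below, with 2530 above and 1799 below at 1 h, 1294 and 573 at 3 h, and 1769 and 889 at 48 h. At 6 h there were 1890 above and 1764 below, at 12 h 1294 and 819, and at 24 h 1164 and 1103. At 3 h, 69.3% of the genes were above, and 58% with the size factors of DESeq2, which also turned the majority to genes below at 6 h (42.1% above) and 24 h (48.3% above). Requiring a 1.5-fold difference from each parent left 895 genes at 0 h, 1191 at 1 h and 787 at 48 h, turned the majority at 0 h to genes above, 615 against 280, and turned it to genes below at 12 h, 261 against 203, and at 24 h, 418 against 337. Leaving out the libraries of replicate 3 lowered every count by over 1.5 times, to 2060 at 0 h and 1181 at 48 h, and leaving out those of replicate 2 gave 2133 at 1 h.

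**Figure D5:**
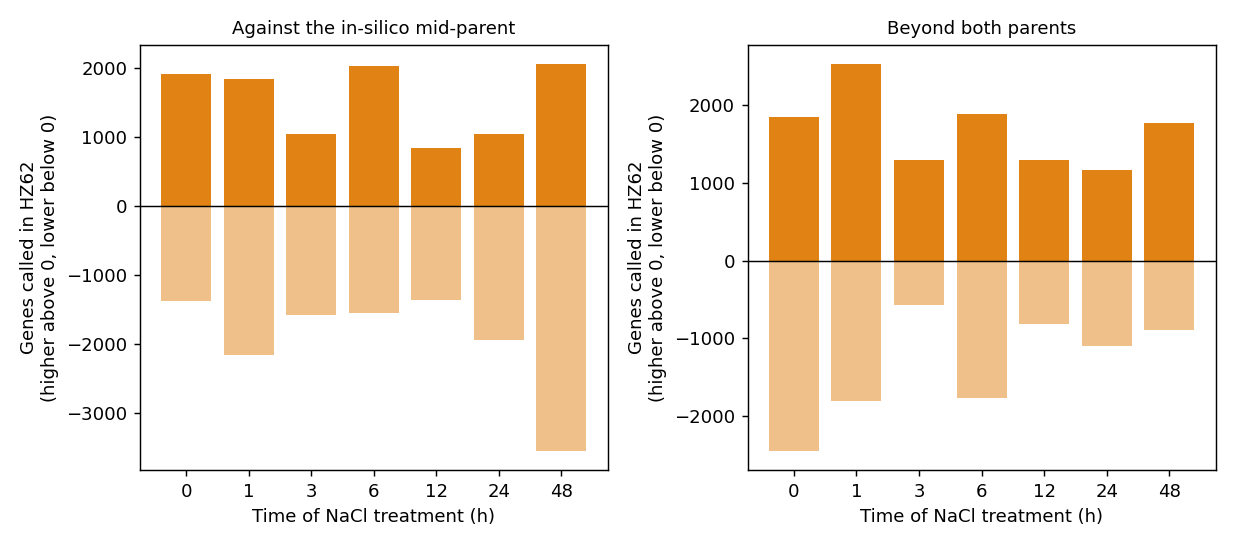
Number of genes in HZ62 (vertical axis, higher above 0 and lower below 0) that differed from the averaged parental libraries (left) or from both parents in the same direction (right) at each time of NaCl treatment in hours (horizontal axis), with 3 libraries per group. At 48 h, 2055 genes were higher and 3550 lower than the arithmetic parental average (5849 and 1726 on the log2 scale), and 1769 were above and 889 below both parents.

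The salt response of HZ62 was also set against the mean of the parental log2 responses. It differed at 2308 genes at 1 h, 2395 at 3 h, 1394 at 6 h, 1841 at 12 h, 2845 at 24 h and 1378 at 48 h in the edgeR interaction test. At 1 h 1742 of the 2308 genes had the lower change in HZ62, and at 24 h 2226 of 2845. Of these, 679 at 1 h and 519 at 24 h lay in the 4 blocks with most genes over 8-fold higher in B409, as did 706 of the 1795 genes with the lower change at 3 h. Without the 3099 genes at least 8-fold higher in B409, 1383 genes were left at 1 h and 1434 at 3 h. Without the libraries of replicate 3, 827 were left at 6 h, 1218 at 12 h and 814 at 48 h. A hybrid at the arithmetic mean of its parents can differ from the mean of their log2 responses where the parents differ in level. The counts, and the majorities with the lower change in HZ62, therefore do not measure a departure from the arithmetic mean. The simulated counts, with a single mean per parent for all times, could not show this. Among the 8543 genes whose parental responses differed at 48 h, the response of HZ62 was closer to that of 2063A for 73.1%, with a median position of 0.308 (quartiles 0.126 and 0.521) on the scale from 2063A to B409. For 78.1% of these genes the change was larger in size in B409. Across all tested genes, Pearson's correlation of the log2 changes of HZ62 at 48 h was higher with B409, 0.781, than with 2063A, 0.671. These 48 h values rest on the time labels of B409, where an exchange with 24 h stays open. At the earlier times the median positions were 0.688 at 1 h, with 41.1% of the genes closer to 2063A, 0.578 at 3 h (42.4%), 0.524 at 6 h, 0.5 at 12 h and 0.514 at 24 h. Without the genes of the 4 blocks with most genes over 8-fold higher in B409, which leaves in the 210 of the 780 B409-type genes that lie outside them, an alternative chosen after the data were seen, the positions were 0.39 at 1 h (57% closer to 2063A), 0.509 at 3 h (48.9%), 0.435 at 24 h and 0.302 at 48 h.

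The A subgenome gave a smaller part of the counts in B409 than in 2063A, with HZ62 between them. Its share was 48.97% ± 0.41 in 2063A, 46.76% ± 0.23 in B409 and 47.89% ± 0.41 in HZ62 (SD, n = 21 libraries each). B409 minus 2063A was −2.21 percentage points, HZ62 minus 2063A −1.07 and HZ62 minus B409 1.14. Each had p = 1e-05 in a two-sided permutation test within times, which is the smallest p that 100000 draws can give. Without the genes of the chromosome blocks, an alternative chosen after the data were seen, the differences were −0.82, −0.37 and 0.45. In salt, the A share of 2063A went from 49.7% ± 0.07 at 0 h to 48.53% ± 0.044 at 48 h, and that of HZ62 from 48.22% ± 0.031 to 47.21% ± 0.033 at 12 h (SD, n = 3). Without the 100 genes with most counts, the change of 2063A at 48 h was −0.75 points in place of −1.18, and that of HZ62 at 12 h −0.85 in place of −1, while without the genes of the chromosome blocks they were −1.49 and −1.16. With all genes, −1.18 and −1 were the largest changes of these materials. In HZ62 the share moved by 0.07 points at 1 h, 0.06 at 3 h and −0.13 at 24 h, and in B409 by 0.1 at 1 h, −0.02 at 6 h (0.04 without replicate 2) and −0.56 at 48 h. Of these, the changes of HZ62 at 24 h and B409 at 1 h turned to 0.05 and −0.2 without the 100 genes with most counts, and those of HZ62 at 1 and 3 h were 0.16 and 0.17 without the genes of the chromosome blocks. Without the 100 genes with most counts, the changes of HZ62 at 3 h and B409 at 6 h were 0.01 and −0.13. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1. The changes of 2063A at every time, HZ62 at 6, 12, 24 and 48 h and B409 at 12 and 48 h all reached this floor. After Benjamini-Hochberg adjustment over 18 comparisons, the p of this test was 0.15 for each of them, so it does not single out any.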

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

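The explanations for the B409-type transcripts and for the chromosome blocks, and exchanged time labels in B409, were tested only after those results were seen, and the 100 regroupings for genes beyond both parents, with all those that place 3 libraries of 1 material under the hybrid's label, were drawn after a smaller set had been seen, while the tests of depth, single libraries and repeated times for B409 at 48 h and the other splits of the libraries for the remaining comparisons were set beforehand.

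Tests of the difference itself called genes between the salt responses of the materials at every time tested. As no library without salt was taken after 0 h, these are differences in change with salt, age and hour of day together. Between the parents the edgeR interaction test called 2629, 6076, 3230, 3922, 4951 and 8543 genes at 1, 3, 6, 12, 24 and 48 h. Between HZ62 and the mean log2 response of its parents it called 2308, 2395, 1394, 1841, 2845 and 1378 genes at the same times. A hybrid at the arithmetic mean of its parents can also be called there. The 4 blocks with most genes over 8-fold higher in B409 held 1413 of the 58909 tested genes. Of the calls between the parents they held 28.4%, 13.9% and 12.6% at 1, 3 and 24 h. Of those for HZ62 they held 30.2%, 30.7% and 19.1%. At these times the 2063A libraries held B409-type transcripts. When the libraries of a time and of 0 h were exchanged in the same way in each material, which allows 10 splits, 1 split in each of these 12 comparisons, the real one, gave as many genes. The highest of the other splits gave 12 genes between the parents and 0 for HZ62. With 10 splits no share under 0.05 can be reached. In addition, each other split mixes the libraries compared within its groups, so their real difference becomes spread there and lowers the count. The gap to the real count therefore does not decide on chance or test whether the responses differed. Both limits apply to the salt comparisons, with 5143 to 20818 genes against at most 1262 in another split, to the parental differences, with 11215 to 17336 against at most 2248, and to the mid-parent comparison, with 2194 to 5605 against at most 171. For genes beyond both parents, 100 regroupings of the 9 libraries were counted, the real one included. From 0 to 48 h, 3, 9, 21, 7, 14, 14 and 9 of the 100 gave as many genes as the real one. The real values were 4292, 4329, 1867, 3654, 2113, 2267 and 2658, and the highest of the other draws 5355, 8425, 23079, 20819, 22650, 22370 and 29136. The draws that reached the real value all placed at least 2 libraries of 1 material under the hybrid's label, and of all 29 other regroupings with 3 libraries of 1 material there, 20 reached it at each time, with up to 18675 genes at 0 h. Such regroupings count the difference between the materials again, so this count does not decide on chance at any time. Without the libraries of replicate 3 the count at 0 h was 2060. Regroupings with several times the real count point to the structure of the materials in these libraries.

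One pattern is the presence of B409-type transcripts in the 2063A libraries of 1, 3 and 24 h. RNA or reads of B409 or HZ62 mixed into the libraries would raise all these genes alike. At 24 h the genes of the C01 end had a median of 1.09% of the HZ62 level (bootstrap interval 0.893 to 1.35) and those of the C09 end 22.4% (21.4 to 23.3). The intervals resample genes of the mean over 3 libraries. They treat neighbouring genes as independent and hold no spread between libraries. By library, the summed share at 24 h ran from 1.31% to 2.68% at the C01 end and from 21.4% to 22.9% at the C09 end. At 3 h these 2 ends were alike, at 23.8% (20.2 to 27.8) and 20.9% (20.3 to 21.7), but the C02 start, with 22 genes, had 0.856% (0.37 to 2.06). At 1 h the C01 end had 25.7% (22.9 to 28.3) and the genes outside the blocks 1.02% (0.623 to 1.81), while the medians of the C02 and C09 ends were 14% and 14.3%. Mixing as the whole cause is thus argued against at each of these times. Reads of other genes counted at these genes would give the same share at each time if their source and the HZ62 level did not change. The left part of the C02 end stood at 0.981% ± 0.945 at 24 h and 21.8% ± 0.492 at 3 h (SD, n = 3), with 0.442% at 24 h without replicate 3, whose library stood at 2.06%. This argues against a constant share of such reads at these genes, while a source that changed with time was not tested. A candidate explanation that stays open is that plants of unlike genotype were pooled under the 2063A label, some carrying B409 segments: the share stepped from 0.981% to 21.5% ± 0.346 at one position on C02 at 24 h, with 13.7% ± 1.48 and 12.7% ± 0.45 on its sides at 1 h. The test leaves it undecided, because the sides also differed at 3 h, 21.8% ± 0.492 against 17.3% ± 0.396. Each of the other times searched had its largest step elsewhere on C02, at 0 h (0.431% to 6.68%), 1 h (13.9% to 22.5%, with 15 genes on the right and quartiles of 8.24% and 45.1% there) and 3 h (19.9% to 10.5%). This is a hypothesis found and tested on the same libraries, and an effect of salt on these segments in 2063A was not tested apart from it.

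Another pattern is the number of genes changed in B409 at 48 h. Depth is argued against, since after thinning every library to the lowest total B409 still had 1.96 times the larger count of the other materials, 15517 against 7916. A single deviating library is argued against, since leaving out any of the 6 libraries left at least 15993 genes. At least 3233 genes separated the 48 h libraries of B409 from each other time, the nearest being 24 h. This argues against the libraries of a time being given again as 48 h, but the bound set beforehand was wrong for other mistakes of labelling, since an exchange of labels leaves the count unchanged. An exchange with 1, 3, 6 or 12 h is argued against, since each B409 library of these times resembled its own time in HZ62 and 2063A more than 48 h, by a difference in correlation (log2 changes from 0 h over all tested genes) of at least 0.173. An exchange with 24 h stays open. The 24 h libraries of B409 resembled 48 h slightly more in HZ62 (lowest difference -0.019) and 24 h more in 2063A (differences of 0.072 to 0.074). A genotype difference in the course of the response remains open and may account for it, as may a difference in the handling of these plants, which the labels do not record.

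The last pattern is the blocks expressed mainly in one parent. Sequence variants through which reads of 2063A from the C blocks are lost altogether would leave the homoeologous A regions unchanged, whereas variants that divert these reads to the A copies would raise them. For the C01 and C09 ends the values go against loss alone, since the last 100 expressed genes of A01 and A10, taken by position, had median log2 ratios of B409 to 2063A of −0.72 (bootstrap interval over genes −0.81 to −0.58) and −0.82 (−0.97 to −0.72). Among the ends of the A chromosomes these medians were the lowest, and the highest was 0.24. However, the A10 genes lie inside the A10 block and most of the A01 genes inside the A01 block. Both blocks had been found by their shift in the same libraries, so this is no independent test. For C02 loss alone stays open. The last 100 genes of A02 had a median of −0.17 (−0.31 to 0.02), while 46% of the last 100 genes of C02 were over 8-fold higher in B409 and 38% in 2063A, and the first 100 genes of A02 had one of −0.16 (−0.3 to −0.07). The A02 blocks from 29669692 to 34369001 and from 1588748 to 2063893 go against loss alone, with medians of −1.11 (quartiles −1.79 and −0.71) and −0.96 (−1.44 and −0.61), but they were chosen for a shift and their pairing with the C02 genes was not given. Exchange of segments between homoeologous chromosomes is a candidate explanation that came from the place of the blocks: 3 of the 3 A blocks with most genes raised in 2063A lie on A01, A02 and A10, which correspond to C01, C02 and C09. As this was seen first, it adds no support. Reads of C copies counted at the A copies, through such variants or not, cannot be told apart from a real gain, because pairs of copies were not given and the spread of ratios in the A10 block (interquartile range 0.85) fits either. The exchange is a hypothesis, since the genomic samples of the series were not analysed here.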

How the results depend on the processing

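The alternatives that leave out genes 8-fold higher in B409 or the chromosome blocks, thin the libraries or restrict the times, those that leave replicates out of the A share and the single-parent genes, and all those applied to the overlaps between materials were chosen after the data were seen. Thinning is listed here as an alternative for all salt counts. Its bound as the depth test of B409 at 48 h was set beforehand. All salt, parental and overlap counts stayed within 1.5 times of the reported value under every alternative run, and the 96 alternative values of the 4 named IDs stayed past the thresholds in the same direction. Without the 8-fold genes, the response difference between parents at 1 h fell to 1597 genes and that of HZ62 to 1383 at 1 h and 1434 at 3 h, by construction, as genes were removed. Leaving out each replicate number in turn, with fewer samples per group, gave 1617 to 2580 genes between the parents at 1 h, and for the response of HZ62 827 to 1166 at 6 h, 1218 to 1977 at 12 h and 814 to 1148 at 48 h. Genes beyond both parents then ranged, from 0 to 48 h, over 2060 to 3457, 1869 to 5270, 861 to 1711, 1704 to 3074, 862 to 1974, 1070 to 1851 and 1181 to 2141. The 1.5-fold minimum left 895, 1191, 497, 1073, 464, 755 and 787 of them, since small differences no longer counted. The log2-scale mid-parent gave 6735, 6384, 4771, 6926, 5479 and 5122 genes from 0 to 24 h, as the mean of logs lies below the log of the mean. The DESeq2 Wald test gave 1459 mid-parent genes at 12 h, and the cause was not tested. The change of the A share reversed without the 100 genes with most counts in B409 at 1 h (−0.2 points in place of 0.1) and HZ62 at 24 h (0.05 in place of −0.13), and in B409 at 6 h without replicate 2 (0.04, within −0.08 to 0.04 over the 3 replicate numbers, with −0.02 reported and p = 0.7 in the exact permutation test). The cause was not tested. With the libraries of 6, 12 and 48 h alone the A share differed by −2.15, −1.31 and 0.85 points between B409 and 2063A, HZ62 and 2063A, and HZ62 and B409. With the replicate block, all counts were 0.984 to 1 times the reported ones, so it changed none of them by over 1.5 times. The replicate numbers do not pair the libraries: in 0 of 210 pairs of groups were all same-number correlations over 0.1, and 26 of 63 libraries correlated best with their own number. Alternatives for gene lists (an estimated correlation, fry and the block) were not run, because no list could be matched. Thinning every library to the lowest total gave 0.905 to 0.955 times the reported salt counts.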

Other observations

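The values given here were looked up after the main results were seen, and they carry no test beyond the calls already described. Counts were spread over more genes after 12 h of salt than before it in each material. The 100 genes with most counts in a library held 17.6% ± 1.07 of all counts in 2063A at 0 h and 9.72% ± 0.501 at 12 h, 16.5% ± 0.15 and 9.39% ± 0.025 in B409, and 16.1% ± 0.115 and 10.1% ± 0.0764 in HZ62 (SD, n = 3). At 48 h this share was 14.6% ± 0.0755 in 2063A and 11.9% ± 0.126 in HZ62, but 9.52% ± 0.054 in B409. At 3 h it stood at 14%, 14.6% and 14.7% in 2063A, B409 and HZ62.

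The genes that changed in salt were also counted by subgenome, both directions together. At 3 h, 30.1% of the 27664 tested genes on A chromosomes and 29.1% of the 30919 on C chromosomes changed in HZ62, 28.4% and 27.5% in B409, and 35.2% and 35.6% in 2063A. At 1 h the part was 11.1% on A and 12.8% on C in 2063A, where the C blocks with B409-type transcripts lie, and 8.99% and 8.45% in HZ62. In 2063A at 24 h, 2937 genes rose and 2407 fell on A, and 3961 rose and 2272 fell on C, where 683 of the genes that rose lay in the 4 blocks with B409-type transcripts. Across genes, which are not independent replicates, Pearson's correlation of the log2 changes at 48 h was 0.781 between B409 and HZ62, 0.671 between 2063A and HZ62 and 0.556 between the parents, and Spearman's was 0.734, 0.698 and 0.565. At 12 h the Pearson values were 0.838, 0.809 and 0.751.

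The ends of C02 and C09 carried blocks of opposite direction. On C02 the block expressed mainly from B409 ends at 64374965 and the block expressed mainly from 2063A begins at 64423384, reaching 65266832. On C09 the block near the start, 197345 to 1279687, was expressed mainly from 2063A and the block near the end, 63855362 to 68379807, from B409. Among the first 100 expressed genes of C04, 20% were over 8-fold higher in 2063A and 0% over 8-fold higher in B409. Blocks expressed mainly from 2063A held 176 of the 1140 genes over 8-fold higher in 2063A, 15.4%, whereas those expressed mainly from B409 held 50% of the corresponding B409 genes.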
